A study of Mus musculus with 8 samples.

How the data were processed

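RNA of 8 spontaneous ovarian tumours, 4 from Nedd9-WT and 4 from Nedd9-null TgMISIIR-TAg mice, was profiled on Agilent mouse arrays. Per the labels' protocols, tumours were followed by magnetic resonance imaging, tissue was frozen, RNA was prepared with RNeasy columns, and 500 ng was amplified and labelled with Cy3. The labels differ on tumour size: the series' design places the burden under 2000 mm3, and the growth protocol has mice killed once the mass had reached that volume. Groups and replicate numbers were taken from the sample titles, and each sample is 1 mouse.

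The deposited scanner files hold intensity values for 1 colour, made per the submitters' processing notes and the file headers with Agilent Feature Extraction 9.5.3. Per the file headers, the processed intensity was background-subtracted and detrended within each array, and it was not normalized between arrays; low values were replaced by a surrogate on 2413 to 6282 spots per array. The deposited value table holds log2 values. From the values, it follows the log2 of the median spot signal (r = 0.999 or higher per array, against 0.978 to 0.987 for the processed signal), all columns share a median of 8.24, and sorted values nearly coincide, as after quantile normalization; the authors' background step for this table stays unknown, and it was used as an alternative. The columns of each spot file that give outlier, saturation and background flags were used as such. The genome build of the probe coordinates, mm9, is that of the file headers.

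Each array has 44397 spots, of which 1377 are controls and were left out. Spots marked as non-uniform or population outliers were left out (194 to 292 per array), saturated spots (15 to 42) were kept, and spots of a probe were averaged, which gave 39429 probes. Values were log2 of the processed signal minus the 75th percentile of each array. That percentile was 2418 to 3552 in signal, and the median spot variation was 2.75% to 3.48%. The 27 probes without a value on every array were dropped. Probes well above background on at least 3 of the 4 arrays of a genotype were kept (31783), and each gene was represented by the probe with the highest mean over all arrays, which left 25535 genes, 5192 of them with more than 1 kept probe. In 11 genes, kept probes differed in direction at an unadjusted p under 0.05. Gene names were updated through a RefSeq gene table of assembly GRCm38.p6, used for names alone: 26055 probes matched by accession, 3195 by symbol and 930 by synonym, and 9249 kept the name in the files.

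The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, prior degrees of freedom 1.84), with Benjamini-Hochberg adjustment and a threshold of 0.05, and values were read with the data.table package, version 1.17.8. Nedd9 was also tested by an exact permutation of the 8 arrays. The 32 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. A gene that was not well above background on any array of a genotype was given a lower bound of its fold: the mean of the brighter genotype against the mean, per array, of the higher of the probe's own value and the lowest value well above background. Replicates were compared before averaging, and the highest correlation between 2 arrays was 0.984.

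Genes named in the text follow a rule fixed, with the lists, the tests and most alternatives, before the data were examined. It takes Nedd9. It takes up to 12 genes per direction with the largest change among described genes past the threshold whose genotypes do not overlap and which are above background on at least 2 arrays of each genotype. It takes up to 4 genes per direction at background in all arrays of a genotype and, if a direction has fewer than 6, the described genes with the smallest p up to 6. From each list it takes up to 4 members with the smallest p. Which of the genes given by the rule were printed was decided after their values had been seen, in part to keep the number of values in the outlier test small. That test covered the 32 list scores, 5 measures of each array and the printed genes. Genes named after their values were seen and those of the Sertoli cell list were not in it. The 3 genes of the transgene context were fixed by name. Genes of a further list, of Sertoli cells, were chosen after the data had been seen.

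The fit was checked on 10 simulated data sets that kept the means and residual spread of the 25535 genes of this comparison and changed a small part of the genes. Genes were simulated as independent, so the check says nothing on lists whose members vary together; the estimated correlation reached 0.816 in the lists that passed. The fit recovered 16.8% of genes changed by 1 log2 unit, 57.4% of those changed by 2 and 82.2% of those changed by 4, with 4.77% false calls, and camera called 100% of lists shifted by 1 log2 unit and 3 unshifted lists. Alternatives were another background correction (normexp, offset 50), quantile or median scaling, no filter or a stricter filter on dim probes, other ways to combine probes, the deposited log2 values, the replicate number as a block, other variance models, array weights, other thresholds and leaving out each array. The 2 slides each hold 1 genotype, so a slide term could not be fitted. Leaving out each array was fixed beforehand, and the choice to print the fit without Nedd9-null replicate 1 for the lists that passed, and for some others, was made after seeing the data.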

Results

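Gene expression was measured in ovarian tumours that arose spontaneously in female TgMISIIR-TAg mice, in which the promoter of Amhr2 (the Muellerian inhibiting substance type II receptor, MISIIR) drives the SV40 large T antigen. The mice had a C57BL/6J background, were not treated with a drug, and were either wild type for Nedd9 (Nedd9-WT, 4 mice) or carried a null genotype (Nedd9-null, 4 mice). NEDD9 is a scaffold protein of the CAS family that binds focal adhesion kinase and SRC. Each tumour was hybridised to 1 Agilent array in 1 colour, so that the number of arrays limits the precision. Between 72.9% (Nedd9-WT replicate 2) and 84.6% (Nedd9-null replicate 1) of the 39429 probes were well above background. Levels below are log2 signals relative to the 75th percentile of each array, given as mean ± SD with n = 4 mice per genotype, and differences are Nedd9-null minus Nedd9-WT with the standard error (SE) of the limma fit.

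The first question was whether the targeted transcript was reduced in the tumours labelled Nedd9-null. Nedd9 was 1.28 ± 0.42 in Nedd9-WT and -3.23 ± 0.86 in Nedd9-null tumours, a difference of -4.51 (SE 0.44), or 22.9-fold lower. The 4 Nedd9-null tumours had -2.01, -3.50, -3.39 and -4.03, and the 4 Nedd9-WT tumours had 1.15, 0.84, 1.30 and 1.85. Every Nedd9-null value was below every Nedd9-WT value (two-sided exact permutation p = 0.0286, the smallest that 70 arrangements can give; limma adjusted p = 0.0281). Nedd9-null replicate 1 had the highest of the 4 null values, with a processed signal of 601 against 217 to 310 in the others and 5694 to 10680 in Nedd9-WT. The array has a single Nedd9 probe, at chromosome 13, 41405822 to 41405881 (mm9, minus strand), with the sequence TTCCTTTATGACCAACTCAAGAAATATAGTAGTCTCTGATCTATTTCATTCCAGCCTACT. It was well above background on all 8 arrays. The labels do not say which exons the null allele lacks, so it is not known whether the probe lies in the deleted part.

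The main comparison asked which genes differ between Nedd9-null and Nedd9-WT tumours. Besides Nedd9, the meiotic recombinase gene Dmc1 was lower in Nedd9-null tumours, while Podxl, Lin7a, Acss3, Slc1a2, Dydc1, Abcb11 and Gtsf1l were higher. Podxl, which encodes the sialomucin podocalyxin, was 1.51 ± 0.19 in Nedd9-null and -0.70 ± 0.35 in Nedd9-WT tumours, 4.61-fold higher (log2 difference 2.20, SE 0.21, limma adjusted p = 0.0281). Lin7a, a scaffold gene of epithelial polarity complexes, was higher by 3.58 (SE 0.39, limma adjusted p = 0.0363). Dmc1 was -5.53 ± 0.63 in Nedd9-null and -0.87 ± 0.70 in Nedd9-WT tumours, 25.3-fold lower (-4.66, SE 0.43, limma adjusted p = 0.0281).

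Several of the other genes that rose were dim. Acss3, a short-chain acyl-CoA synthetase gene, was not well above background on any Nedd9-WT array and was at least 14.3-fold higher in Nedd9-null tumours (limma adjusted p = 0.0319). The same held for Dydc1 (at least 4.70-fold), for Abcb11, the bile salt export pump (at least 3.63-fold), and for the uncharacterised Gm281 (at least 4.83-fold), with limma adjusted p of 0.0281, 0.0281 and 0.0457. Each bound set the Nedd9-null mean against the lowest signal that counted as well above background on the Nedd9-WT arrays, and holds for the processed signal alone. With normexp background correction the log2 differences of Acss3, Dydc1, Abcb11 and Gm281 were 2.05, 1.09, 1.01 and 1.00, and of these Acss3 alone passed. Slc1a2, a glutamate transporter gene, was well above background on 1 of 4 Nedd9-WT arrays and on all 4 Nedd9-null arrays (3.35, SE 0.33, limma adjusted p = 0.0281). Gtsf1l, well above background on 3 of 4 Nedd9-WT arrays, was higher by 2.52 (SE 0.30, limma adjusted p = 0.0480). The differences of these dim genes depended on the background: with normexp they were 0.88 for Slc1a2 and 1.22 for Gtsf1l, and neither passed (ranges over all alternatives 0.88 to 3.56 and 1.22 to 2.75). The Podxl probe lies at chromosome 6, 31470405 to 31470464, the Lin7a probe at chromosome 10, 106857236 to 106857295, and the Dmc1 probe at chromosome 15, 79392424 to 79392483 (mm9). Acss3 lies near Lin7a on chromosome 10, with its probe at 106425881 to 106425940. So does B230114P17Rik (106370604 to 106370663), also higher past the threshold and named after its value was seen. Whether these neighbouring genes changed independently was not tested. Exon and UTR positions were not assigned here.

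Of 25535 genes tested, 17 passed an adjusted p of 0.05, 15 of them higher and 2 lower in Nedd9-null tumours, and in all 17 the 4 values of each genotype did not overlap. Such separation occurred in 3254 genes (12.7%, 1829 higher and 1425 lower), where chance gives 2.86% on average. An unadjusted p under 0.05 was found for 6100 genes, against 1277 expected by chance on average. Genes vary together across these arrays, so a single split can exceed both by far without an effect of genotype. Neither count was made for other splits. The lower genes with the next smallest p did not pass. Fdxr, which encodes the ferredoxin reductase that feeds electrons to steroidogenic enzymes, differed by -2.16 (SE 0.27, limma adjusted p = 0.0587), and Cox6a2, a cytochrome oxidase subunit gene, by -3.28 (SE 0.45, limma adjusted p = 0.0596). The homeobox gene Vax1 differed by -4.77 (SE 0.66) and the neuronal tubulin gene Tubb3 by -1.36 (SE 0.20), both with a limma adjusted p of 0.0596. The count rested on single arrays: it was 4773 without Nedd9-null replicate 1, 42 without Nedd9-WT replicate 1, 2 without Nedd9-null replicate 4, and 0 without any of the other 5 arrays. It was 0 with a plain equal-variance test, 4 with the median or with quantiles as the scale, and 7 with only genes above background on all 8 arrays, and each genotype lay on a slide of its own, so that slide and genotype cannot be told apart.

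**Figure D1:**
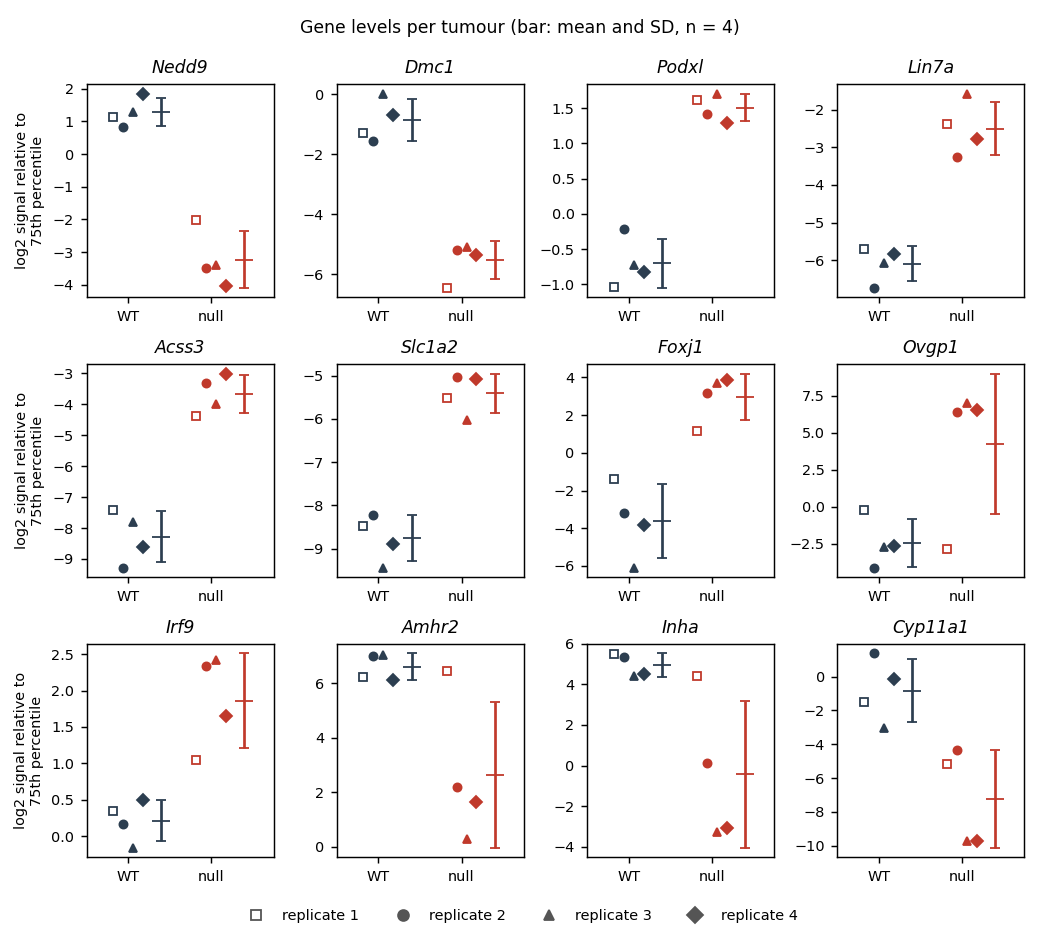
Levels of 12 genes in each tumour, as log2 signal relative to the 75th percentile of the array (vertical axes differ between panels), for Nedd9-WT and Nedd9-null tumours; symbols mark the replicate and bars give the mean and SD of 4 tumours. Nedd9 and Dmc1 were low in all 4 Nedd9-null tumours, whereas Ovgp1, Amhr2 and Inha in Nedd9-null replicate 1 (-2.82, 6.46 and 4.44) were near the Nedd9-WT levels.

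The arrays of the Nedd9-null group were not alike. Over the 25535 genes, Nedd9-null replicate 1 correlated with the Nedd9-WT arrays at 0.938 to 0.973 and with the other 3 Nedd9-null arrays at 0.886 to 0.920. Correlations were 0.954 to 0.980 between Nedd9-WT arrays and 0.977 to 0.984 between Nedd9-null replicates 2 to 4. The first principal component held 58.1% of the variance and placed Nedd9-null replicate 1 at -68.0, among the Nedd9-WT tumours (-104 to -52.0), and replicates 2 to 4 at 113 to 151. On the second component (17.8%) Nedd9-null replicate 1 was at 111, outside the Nedd9-WT range of -101.5 to 42.5. For that reason the score of this tumour, and the fit without it, are given below beside each list that passed.

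**Figure D2:**
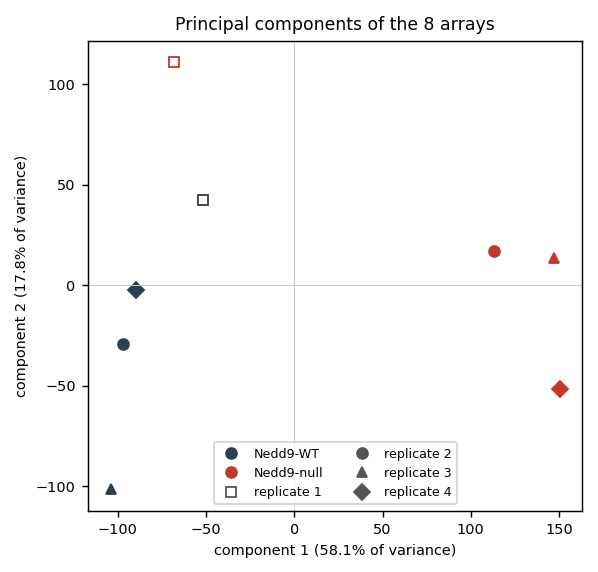
The 8 arrays on the first (58.1% of variance, horizontal) and second (17.8%, vertical) principal components of 25535 genes, in arbitrary units; colours mark the genotype and symbols the replicate. Nedd9-null replicate 1 lies at -68.0 on the horizontal axis and the other 3 Nedd9-null arrays at 113 to 151. On the vertical axis Nedd9-null replicate 1 lies at 111, above all other arrays.

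Gene groups fixed before the data were examined were compared next, to ask which cell types and programmes differ between the genotypes. Genes of ciliated oviduct cells had the largest median difference of the 32 lists, 4.58, and all 16 measured members were higher in Nedd9-null tumours. Foxj1, the regulator of motile cilia, differed by 6.58 (SE 1.02, 95.7-fold), Dynlrb2, a dynein light chain gene, by 6.59 (SE 1.41), Tppp3 by 3.98 (SE 0.71) and the ciliary gene Cfap126 by 3.81 (SE 0.89). The list passed limma's camera (adjusted p = 7.68e-09) but not with an estimated correlation (adjusted p = 0.914); 0 members passed over all genes and 15 when adjusted over the list alone. With Nedd9-null replicate 1 left out, all 16 passed over all genes, and the median was 5.90. The list score, the mean log2 difference from the Nedd9-WT mean, was 4.69 ± 2.43 in Nedd9-null tumours. It was 1.08 in Nedd9-null replicate 1, below Nedd9-WT replicate 1 (1.78), and 5.42, 6.02 and 6.24 in the other null tumours.

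The interferon response list was also higher in Nedd9-null tumours, by a median of 1.77, with 24 of 25 genes positive. Irf9, a subunit of the transcription factor that type I interferon activates, differed by 1.65 (SE 0.33), and all 4 Nedd9-null values lay above the Nedd9-WT values. The interferon-induced genes Ifit1, Ifit2 and Ifih1 differed by 3.45 (SE 1.05), 2.14 (SE 0.63) and 1.44 (SE 0.46). The list passed limma's camera with an adjusted p of 3.65e-06 (adjusted p = 0.958 with an estimated correlation), with 0 members past the threshold over all genes and 1 adjusted over the list alone. Leaving out Nedd9-null replicate 1 gave 21 of 25 interferon genes past the threshold over all genes and a median of 2.70. The score of Nedd9-null replicate 1 was -0.28, within the Nedd9-WT range of -0.71 to 0.45, and the other 3 had 3.23, 2.97 and 1.71. Antigen presentation genes were higher by a median of 0.60, 17 of 18 positive (camera adjusted p = 0.0166; adjusted p = 0.958 with an estimated correlation). The proteasome activator genes Psme1 and Psme2 differed by 0.89 (SE 0.18) and 0.85 (SE 0.21) and the peptide transporter gene Tap1 by 0.81 (SE 0.32). Of this list, 0 members passed over all genes and 2 adjusted over the list alone; its score in Nedd9-null replicate 1 was -0.49, and without that array 5 passed over all genes. The call was lost without Nedd9-null replicate 2, Nedd9-null replicate 3 or Nedd9-WT replicate 4 (camera adjusted p = 0.133, 0.0630 and 0.213). The probes of Irf9, Psme1 and Psme2 lie close together on chromosome 14, from 56228806, 56200194 and 56206296 (mm9). Each of these genes was higher in all 4 Nedd9-null tumours than in any Nedd9-WT tumour. That includes replicate 1, whose scores of both lists were not raised. Whether these neighbouring genes changed independently was not tested.

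Ovarian steroidogenic and follicle cell genes were lower in Nedd9-null tumours, by a median of -2.38 over 21 measured members. Cyp11a1, the first enzyme of steroid synthesis, differed by -6.41 (SE 1.51), and by -7.36 to -4.10 over the alternatives. It was well above background on 2 of 4 Nedd9-null arrays and on all 4 Nedd9-WT arrays. Inha and Inhbb, which encode inhibin subunits, differed by -5.39 (SE 1.60) and -1.94 (SE 0.49), while Fst, the gene of the activin-binding protein follistatin, differed by 2.91 (SE 0.77) in the opposite direction. The list passed limma's camera (adjusted p = 7.94e-04; adjusted p = 0.914 with an estimated correlation), with 0 members past the threshold over all genes and 6 lower and 1 higher adjusted over the list alone. Over all genes, 10 passed lower and 1 higher once Nedd9-null replicate 1 was left out, with a median of -3.03. The score of Nedd9-null replicate 1 was -0.10, within the Nedd9-WT range of -0.97 to 0.60, and the others had -1.96, -3.64 and -3.92.

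Epithelial genes were higher by a median of 0.99, with 22 of 27 members positive. The epithelial transcription factor gene Grhl2 differed by 1.70 (SE 0.32), and the tight junction genes Cldn7 and Cldn4 by 1.79 (SE 0.47) and 0.67 (SE 0.17). The list passed limma's camera (adjusted p = 0.00302; adjusted p = 0.914 with an estimated correlation), and 9 members were higher and 2 lower adjusted over the list alone, against 0 over all genes. In the fit without Nedd9-null replicate 1, 14 passed higher and 2 lower over all genes, and the median was 1.59. Nedd9-null replicate 1 scored -0.17 and the other null tumours 1.85, 1.78 and 1.04; these 3 are the tumours in which the ciliated oviduct cell score was 5.42 to 6.24. Grhl2, Cldn4 and Cldn7 were higher in all 4 Nedd9-null tumours, replicate 1 included.

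Endothelial genes were lower by a median of -0.65, 18 of 20 negative, as were red blood cell genes by -1.89, with all 9 measured members negative. The endothelial genes Eng, Emcn and Erg differed by -0.98 (SE 0.29), -0.73 (SE 0.24) and -1.19 (SE 0.39). Sox17, which both endothelium and oviduct epithelium express, differed by 3.58 (SE 1.26) in the opposite direction. In the red cell list, the haem synthesis gene Alas2 differed by -2.36 (SE 1.17), Hbb-b2 by -2.29 (SE 1.11) and the transferrin receptor gene Tfrc by -1.19 (SE 0.42). Both lists passed limma's camera (adjusted p = 0.00302 and 0.0164; adjusted p = 0.914 for both with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. Without Nedd9-null replicate 1, which had the lowest score of all 8 arrays in both lists (-0.54 and -2.31), neither passed (medians -0.66 and -1.14, adjusted p = 0.147 and 0.192), and 1 endothelial gene passed higher, 1 lower and 0 red cell genes over all genes. The red cell list was also lost without Nedd9-WT replicate 4 (adjusted p = 0.0792), with the median as the scale (0.0649) and with array weights (0.137). Red cell scores overlapped between the genotypes. Nedd9-WT replicate 1 had -1.92, below Nedd9-null replicates 2 and 4 (-1.29 and -1.03), and Nedd9-WT replicate 4 had 1.47. Endothelial scores were -0.54 to -0.33 in Nedd9-null tumours and -0.32 to -0.11 in Nedd9-WT replicates 1 to 3. Nedd9-WT replicate 4 stood higher, at 0.70.

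Cholesterol biosynthesis genes were higher by a median of 0.44, 15 of 21 positive. Insig1, a sterol-regulated brake on cholesterol synthesis, differed by 1.33 (SE 0.20) and the squalene synthase gene Fdft1 by 1.28 (SE 0.21). In both genes all 4 Nedd9-null values lay above the Nedd9-WT values. The list passed limma's camera narrowly (adjusted p = 0.0487; adjusted p = 0.958 with an estimated correlation), with 2 members adjusted over the list alone and 0 over all genes, and Nedd9-null replicate 1 scored 0.07. The call was lost without any of Nedd9-null replicates 2 and 4 and Nedd9-WT replicates 1, 3 and 4 (adjusted p = 0.0561, 0.351, 0.0698, 0.0590 and 0.213). It was also lost with the median as the scale, the mean of kept probes and the replicate block (adjusted p = 0.0649, 0.0756 and 0.0935), whereas without Nedd9-null replicate 1 it was kept, with 6 members higher and 1 lower past the threshold over all genes.

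**Figure D3:**
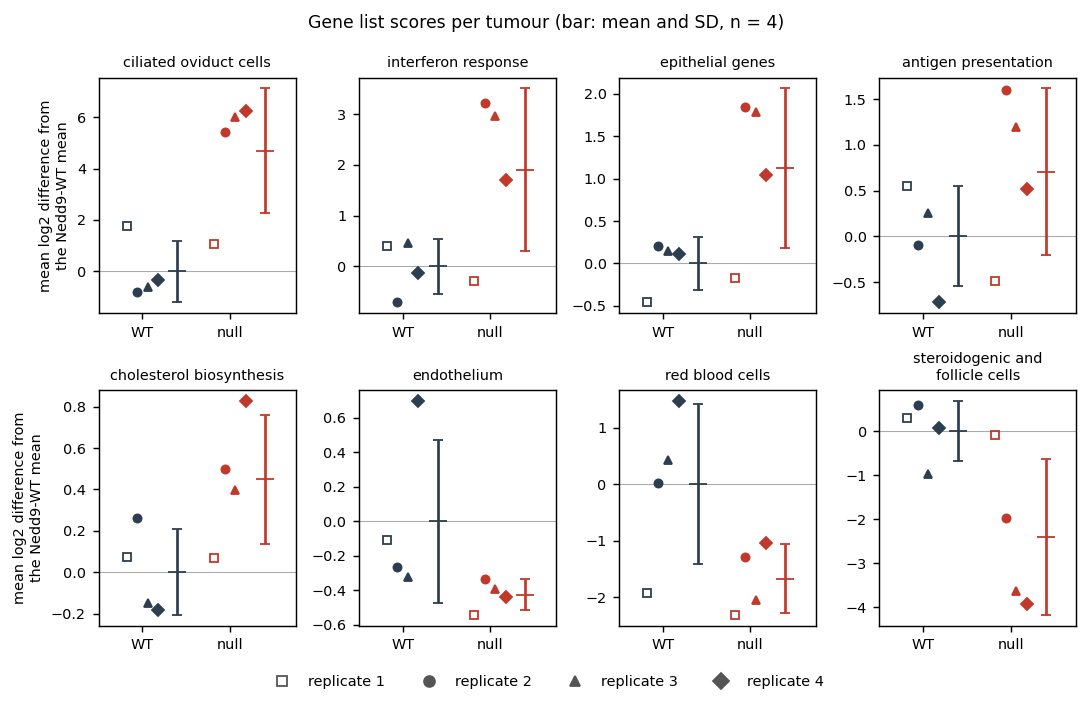
Scores of the 8 gene lists that passed limma's camera, as the mean log2 difference from the Nedd9-WT mean in each tumour (vertical axes differ between panels); symbols mark the replicate, bars give the mean and SD of 4 tumours. The ciliated cell score was 5.42 to 6.24 in Nedd9-null replicates 2 to 4 and 1.08 in replicate 1.

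The title of the series names oncogenic signalling and a stem and mesenchymal signature, and the lists for these did not pass. Mesenchymal genes had a median difference of 0.47 over 29 members (camera adjusted p = 0.870), with members in both directions. Cd44, the hyaluronan receptor gene, differed by 2.66 (SE 0.56), while Cdh2, the gene of N-cadherin, differed by -2.54 (SE 0.61) and the fibronectin receptor gene Itga5 by -1.24 (SE 0.31). Adjusted over the list alone, 1 mesenchymal gene was higher and 2 were lower. Stem cell genes had a median of -0.13 over 27 members (camera adjusted p = 0.690). The drug efflux transporter gene Abcg2 differed by -2.13 (SE 0.37), the retinaldehyde dehydrogenase gene Aldh1a2 by -5.36 (SE 1.80) and Prom1, which encodes CD133, by 4.87 (SE 1.42). In Nedd9-null replicate 1, Aldh1a2 was 3.94 and Prom1 was -5.72, both near the Nedd9-WT means of 3.99 and -5.93. None of these 6 genes passed over all genes. Leaving out Nedd9-null replicate 1, 7 mesenchymal genes passed higher and 4 lower, and 5 stem cell genes higher and 6 lower. The list medians were then 0.54 and -0.31, without a call of either list (camera adjusted p = 0.392 and 0.670).

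Partners of NEDD9 and other CAS proteins had a median difference of -0.00 over 24 members (camera adjusted p = 0.924), with 2 higher and 3 lower adjusted over the list alone. Efs, which encodes another CAS family scaffold, differed by 1.04 (SE 0.22), Ptk2, the gene of focal adhesion kinase, by -0.61 (SE 0.15), and Elmo1, a Rac activation partner, by -2.42 (SE 0.63). Bcar1, a further CAS family gene of the list named after its value was seen, differed by -1.39 (SE 0.39, limma adjusted p = 0.1075). In Nedd9-null replicate 1 Bcar1 was 2.52, near the lowest Nedd9-WT value (2.56). Efs was higher and Ptk2 lower in all 4 Nedd9-null tumours than in any Nedd9-WT tumour, and neither passed over all genes (limma adjusted p = 0.0836 and 0.0957). The Efs probe lies on chromosome 14 (from 55535529, mm9), in the region of the Irf9, Psme1 and Psme2 probes. Whether Efs changed independently of these genes was not tested. Focal adhesion and integrin genes had a median of -0.14 (camera adjusted p = 0.446), with Itgb3 at -2.19 (SE 0.50). Itgb6 was not well above background on any Nedd9-WT array and was at least 5.63-fold higher in Nedd9-null tumours (limma adjusted p = 0.0957), with 3 of 4 null arrays well above background; the bound holds for the processed signal, and with normexp the log2 difference was 1.61. Receptor tyrosine kinase genes had a median of 0.14 (camera adjusted p = 0.870), and of -0.17 without Nedd9-null replicate 1. Axl differed by -1.86 (SE 0.47) and Fgfr3 by 2.97 (SE 0.82). In Nedd9-null replicate 1, Axl was 3.35, Fgfr3 -2.20 and Elmo1 -4.26, near Nedd9-WT replicate 1 (3.54, -1.98 and -4.15). STAT3 targets had a median of -0.24 (adjusted p = 0.446), immediate early genes -0.11 (adjusted p = 0.866), Hedgehog and Notch targets 0.05 (adjusted p = 0.708) and TGF-beta targets -0.18 (adjusted p = 0.140), with the receptor gene Tgfbr1 at -1.63 (SE 0.36), all by limma's camera. The TGF-beta list passed without Nedd9-null replicate 2 (median -0.46, camera adjusted p = 0.0240). Without Nedd9-null replicate 1 the medians were -0.12 for STAT3 targets, -0.23 for immediate early genes and -0.39 for TGF-beta targets. That of Hedgehog and Notch targets was 0.001, and none of these lists passed.

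Proliferation genes differed little. Mitosis genes had a median of -0.03 over 25 members (camera adjusted p = 0.879) and DNA replication genes 0.11 over 25 members (camera adjusted p = 0.870). The cyclin gene Ccnb2 differed by 0.64 (SE 0.21) and the replication gene Gins1 by 0.67 (SE 0.26), without passing over all genes. WNT targets had a median of 0.49 (camera adjusted p = 0.148) and 3 members higher adjusted over the list alone. Among them Sp5 and Apcdd1, direct targets of the pathway, differed by 3.72 (SE 0.66) and 2.74 (SE 0.62), with all 4 Nedd9-null values of both above the Nedd9-WT values. The WNT list score was 0.78 to 0.93 in the 4 Nedd9-null tumours and -0.58 to 0.57 in the Nedd9-WT tumours (exact permutation p = 0.0286, adjusted over 32 lists p = 0.343). The p53 targets had a median of -0.29 (camera adjusted p = 0.140), with the desmosome gene Perp at 2.27 (SE 0.48) and Pmaip1, which encodes NOXA, at -3.13 (SE 0.69). Without Nedd9-WT replicate 1 the p53 list passed, with a median of -0.50 (camera adjusted p = 0.00415). Hypoxia and glycolysis genes had a median of -0.15 (camera adjusted p = 0.330), with the hexokinase gene Hk2 at -3.51 (SE 0.83), and passed without Nedd9-WT replicate 1 (median -0.37, adjusted p = 0.00969) and without Nedd9-null replicate 2 (median -0.24, adjusted p = 0.0278), whereas without Nedd9-null replicate 1 the median was 0.05 (adjusted p = 0.894). The WNT list passed without Nedd9-WT replicate 2 (median 0.41, adjusted p = 0.0126), with the median as the scale (median 0.30, adjusted p = 0.0464) and with every probe by itself (median 0.59, adjusted p = 0.0216), all by limma's camera.

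Markers of other cells the tumour tissue could hold did not pass as lists. The medians were 0.39 for T and NK cells, 0.08 for B and plasma cells, 0.07 for macrophages and -0.06 for neutrophils (camera adjusted p = 0.330, 0.503, 0.870 and 0.503). Hdc, the histamine synthesis gene of mast cells and neutrophils, differed by 3.64 (SE 1.09), without passing over all genes. In Nedd9-null replicate 1 Hdc was -0.63, within the Nedd9-WT range of -1.84 to 0.26. Medians were -0.29 for fibroblasts and extracellular matrix, 0.12 for smooth muscle and pericytes, 0.14 for adipocytes and 0.24 for skeletal muscle (camera adjusted p = 0.446, 0.934, 0.766 and 0.448). The adipocyte median was -1.08 without Nedd9-null replicate 1, which scored 3.14 against -1.01 to -0.00 in the other null tumours, and without it the neutrophil median was 0.18 and the macrophage median 0.42. The fibroblast and matrix list passed without Nedd9-WT replicate 3 (median -0.69, camera adjusted p = 0.00750). The matrix gene Fbln2 differed by -3.05 (SE 0.48). Of the muscle genes, Myh2 was not well above background on any Nedd9-WT array and was at least 7.75-fold higher in Nedd9-null tumours, and Mb, the myoglobin gene, differed by 2.36 (SE 0.57); their limma adjusted p was 0.0756 and 0.0923. The bound of Myh2 holds for the processed signal, and with normexp its log2 difference was 1.54. Of the 11 skeletal muscle genes measured, 7 were higher on average in Nedd9-null tumours. The probe of 2310065F04Rik lies near that of Myh2 on chromosome 11 (from 66925963 and 67010960, mm9). That gene, named after its value was seen, was higher by 2.76 (SE 0.21, limma adjusted p = 0.0281). Whether these neighbouring genes changed independently was not tested. Oocyte genes had a median of -0.57 over 8 measured members (camera adjusted p = 0.281). Ddx4 and Gdf9 differed by -2.28 (SE 0.47) and -1.64 (SE 0.38), and the zona pellucida gene Zp3 by 1.66 (SE 0.26). Ddx4 was well above background on 2 of 4 Nedd9-null arrays, and its difference was -2.60 to -0.86 over the alternatives.

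Genes of the ovarian surface epithelium and the Muellerian tract had a median of 0.14 over 17 members (camera adjusted p = 0.942), again with members in both directions. Ovgp1, the main secreted glycoprotein of the oviduct, was 6.38, 7.01 and 6.53 in Nedd9-null replicates 2 to 4, -2.82 in replicate 1 and -4.11 to -0.21 in the Nedd9-WT tumours. Wfdc2, which encodes the ovarian cancer marker HE4, differed by 5.09 (SE 1.19, limma adjusted p = 0.0912). Its level in Nedd9-null replicate 1 was -3.25, near that of Nedd9-WT replicate 1 (-3.45). Upk1b, a gene of mesothelium and urothelium, differed by -1.87 (SE 0.51). Amhr2, the gene whose promoter drives the transgene, was 6.46 in Nedd9-null replicate 1 and 2.18, 0.29 and 1.64 in replicates 2 to 4, against 6.11 to 7.04 in the Nedd9-WT tumours (difference -3.95, SE 1.19, limma adjusted p = 0.116). The genes of the proteins that T antigen binds differed little: Trp53 by -0.52 (SE 0.18) and Rb1 by 0.68 (SE 0.19), with no overlap between the genotypes and limma adjusted p of 0.149 and 0.105. No probe was identified here as measuring the T antigen transcript itself.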

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

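The tests of a mislabelled tumour, of the slide and of array quality below, and of neighbours of Nedd9 in the last part, were chosen after the result had been seen, and quality was tested by correlations, with a margin added once the value was known, then by the genes that set the array apart; a list score tried after both was set aside, as it restated the pattern; those of oviduct tissue, of dim probes, of spiked-in controls and of other splits were set down before their values were seen. In groups of 4 arrays, a value far from the other 3 was looked for in 224 groups and found in 19, where chance alone gives about 11.2.

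Of these, 6 were in Nedd9-null replicate 1. Sox17 was -3.16 there against 2.26 to 2.48 in the other 3 Nedd9-null tumours, Ovgp1 was -2.82 against 6.38 to 7.01, Dynlrb2 was -0.69 against 3.97 to 4.88, and the score of the ciliated oviduct cell list was 1.08 against 5.42 to 6.24. The oocyte gene Gdf9 was higher there, at -3.21 against -4.63 to -4.52, and more probes were well above background, 33364 against 31356 to 31585. In the other Nedd9-null arrays, Efs in replicate 3 was 3.19 (others 2.56 to 2.64), Trp53 in replicate 3 was -0.91 (others -1.27 to -1.26), and in replicate 2 the score of the STAT3 targets was 0.67 (others -0.71 to -0.51) and that of the p53 targets 0.0328 (others -0.35 to -0.31).

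In the Nedd9-WT group, replicate 3 stood apart in Gtsf1l (-7.44 against -6.77 to -6.73), Inhbb (4.08 against 2.33 to 2.60), Gdf9 (-3.28 against -2.40 to -2.32) and the smooth muscle and pericyte score (-1.49 against 0.38 to 0.60). Replicate 1 stood apart in the scores of the epithelial genes (-0.46 against 0.11 to 0.21), adipocytes (2.49 against -1.06 to -0.46) and p53 targets (-0.52 against 0.11 to 0.21). Tgfbr1 in replicate 2 was 2.19 (others 1.57 to 1.64), and the skeletal muscle score in replicate 2 was -0.46 (others 0.11 to 0.22).

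By its correlations over all genes, Nedd9-null replicate 1 was nearer to the Nedd9-WT tumours than to the other Nedd9-null tumours. A wild-type tumour under a wrong label is argued against by Nedd9 itself, which lay in this array 2.85 log2 units below the lowest Nedd9-WT array. Array quality stays open: of the 8 arrays this one had the lowest 75th percentile (2418), the most spots left out for flags (292), the highest median spot variation (3.48%) and the lowest spike-in slope (0.991), but also the most probes well above background. Of genes over 2 log2 units higher in it than in each other null array, 413 of 839 (49.23%) lay within 1 log2 unit of the Nedd9-WT mean, short of the 50% set to argue against poor quality, and of genes lower by as much, 769 of 1200 (64.1%); its mean correlation with Nedd9-WT was 0.00614 above the lowest between 2 Nedd9-WT arrays (SD 0.00876), which decided nothing. Oviduct tissue in the samples of replicates 2 to 4 is a candidate explanation: Ovgp1 was 6.60 log2 units higher in the lowest of these 3 than in the highest of the other 5 arrays, together with the ciliated cell genes. Tissue with few dividing cells, added to a tumour like the Nedd9-WT ones, would lower the other genes of that tumour together. The steroidogenic score fell to -1.96, -3.64 and -3.92 in replicates 2 to 4. Their mitosis scores did not fall (-0.20, 0.12 and 0.03, Nedd9-WT -0.40 to 0.35). For these lists this argues against dilution by tissue with few dividing cells as the whole cause. Whether oviduct tissue of these mice held few dividing cells was not measured, so dilution by dividing tissue stays open. Oviduct tissue as a cause, in part or as a whole, and tumour cells that took on oviduct features in Nedd9-null mice cannot be told apart here.

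Of the 17 genes past the threshold, 15 were higher in Nedd9-null tumours, and 7 of the 17 lay in the dimmest of 10 equal bins of mean signal. The median difference of that bin was 0.37, far below the changes of 2.20 or more in the genes that rose. This argues against a raised background on the Nedd9-null slide that shifted all dim probes by as much. A smaller shift with signal was present. Medians were 0.20, 0.16 and 0.08 in bins 2 to 4, counted from the dimmest, and -0.13 to -0.02 in bins 5 to 9. The cause of that trend was not tested. The bin medians do not settle single dim genes, which were picked as extremes. The difference of Slc1a2, for example, fell to 0.88 with normexp. The 10 spiked-in control probes, scaled within each array in the same way as the genes, differed by a median of -0.0654. That scaling removes any gain in labelling or hybridisation that spike-ins and genes share. The spike-ins therefore cannot decide whether the slides differed in such a gain. The slide itself cannot be told apart from the genotype, because 0 slides held both.

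Chance cannot be excluded for the count of 17 genes: 2 of the 35 splits of the 8 arrays into 4 and 4 gave as many, and the split that put Nedd9-null replicate 1 with Nedd9-WT replicates 1, 2 and 4 gave 208. That larger count points to a structure of the samples other than genotype. Without Nedd9-null replicate 1, the genotypes differed in 4773 genes, 1 of 35 splits gave as many (the real one), and the highest of the others gave 23. That array was singled out because it stood apart from its genotype, which favours the real split, so these splits do not decide whether chance is excluded. For the gene lists, 32 of 35 splits gave at least the 8 lists of the genotypes, with up to 18 in another split, so chance cannot be excluded for the number of lists.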

How the results depend on the processing

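Nedd9 was lower in Nedd9-null tumours under all 19 alternatives run, from -4.92 without Nedd9-null replicate 1 to -4.25 without replicate 4, and the exact permutation p was 0.0286 in all but the replicate block; limma's adjusted p passed in 12 of 19, and was 0.0876 to 0.124 without any of Nedd9-null or Nedd9-WT replicates 2 to 4 and 0.217 with the block. With the replicate number as a block the difference was -4.51 with an exact p = 0.125, the smallest that 16 sign changes allow, and the count of genes was 0 (4732 at an unadjusted p under 0.05). Tumours of the same number did not deviate together (r = -0.05, -0.23, -0.04 and -0.09, 0 arrays best with their own number). Paired mice need not have tumours that deviate together, so whether the numbers pair the mice stays unknown. The count of 17 genes became 4 with quantile normalization (3 higher), 4 with the median as the scale (2 higher), 7 with genes above background on all 8 arrays (5 higher), 11 with trended robust variances, 0 with the plain equal-variance test, 5984 with array weights (3183 higher) and 1407 at an adjusted p under 0.10 (1049 higher). Median scaling moved the median difference of all genes from 0.03 to -0.16. Leaving out 1 array gave 0 to 4773 genes. With normexp, 22 genes passed and 9 of the 17 were among them; with the deposited log2 values 19 passed and 8 were shared. The 8 lists became 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.245), and leaving out 1 array gave 5 (Nedd9-WT replicate 4) to 9. In 18 of 21 alternatives the number of lists stayed within 1.5 times. The lists themselves changed: without Nedd9-null replicate 2, 8 passed (3 higher and 5 lower), of which 6 were shared. At least 8 lists also passed in 32 of 35 splits of the arrays, so a steady number does not speak for the genotype. Of 1414 values of single genes under alternatives, all kept their direction, 116 gained and 102 lost the threshold. In lists that did not pass, camera's direction turned in 60 of 672 list values without a call, and medians also changed sign where it did not turn (neutrophils -0.28 to 0.48); 8 values gained and 32 lost a call. The cause of these changes was not tested. A slide block was not run, since it could not be fitted. Signal over background limits the dim genes: Acss3, Dydc1, Abcb11, Gm281, Itgb6 and Myh2 have only a lower bound. Slc1a2, Cyp11a1 and Ddx4 were at background on at least 2 arrays of a genotype, and 5 Sertoli cell genes on Nedd9-null replicates 3 and 4.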

Other observations

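Genes that mark Sertoli cells, the supporting cells of the testis, were for the most part well expressed in the Nedd9-WT tumours and in Nedd9-null replicate 1. The idea came from genes seen while the data were examined, among them Inha. The list was written after that and before its own values were looked up; Sox9, Erbb4 and Wt1 were dropped before the test, as they were in other lists or had been seen. The test of neighbours of Nedd9 below was also chosen after the result was seen. Of 21 listed genes all were measured, 20 were well above background on every Nedd9-WT array, and 18 were lower in Nedd9-null tumours. The cystatin gene Cst12 was 3.57 to 5.85 in the Nedd9-WT tumours and 5.19 in Nedd9-null replicate 1, and -0.38, -9.77 and -8.52 in the other 3. The nuclear receptor gene Nr0b1 was 0.46 to 1.52 in Nedd9-WT and 2.29 in Nedd9-null replicate 1, against -3.70, -8.11 and -9.98. On Nedd9-null replicates 3 and 4, 5 of the listed genes were not well above background on either array. The lowest values there are therefore not exact levels. Dhh, the hedgehog ligand that Sertoli cells secrete, was 2.34 to 3.95 in Nedd9-WT and 3.24 in Nedd9-null replicate 1, against -1.27, -1.81 and -2.38, and Defb36 and Cst9 followed the same order. Clu was 6.09 to 6.92 in Nedd9-WT, 6.95 in Nedd9-null replicate 1, and 6.28, 5.14 and 4.58 in the others. Ptgds, Trf and Vnn1 were higher on average in Nedd9-null tumours.

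A candidate explanation is that the Nedd9-WT tumours hold sex cord cells with Sertoli-like features. The list was lower in Nedd9-null tumours by a median of -2.14 (limma's camera p = 4.07e-06; p = 0.159 with an estimated correlation), and 11 members had an unadjusted p under 0.05, none of which was higher. Granulosa or other cells of the ovary also express 6 of the genes, a subset set apart after the result was seen, and the other 15 had a median of -2.99. The score of the list was 0.25 in Nedd9-null replicate 1 and -2.43, -4.15 and -4.25 in replicates 2 to 4. The difference thus lies in these 3 tumours rather than in all 4 of the genotype. The scores of replicates 3 and 4 include 5 genes at background there, so their size is not exact.

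Genes near Nedd9 were looked at for DNA carried along with the null allele. Within 10 Mb of the Nedd9 probe on chromosome 13, 41 of 167 genes (24.6%) had an unadjusted p under 0.05, against 6032 of 25154 elsewhere (24.0%), and a one-sided Fisher's exact test gave p = 0.461. Past the adjusted threshold were 1 of the 167 near genes and 15 of the others, a difference not tested; the near gene, LOC100045978, was named after its value was seen. The question stays open.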
